A study of Mus musculus with 20 samples.

How the data were processed

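Gene expression was measured with Illumina mouse bead arrays in muscle and brain of mice heterozygous for a human mutant TDP-43 transgene and of wild-type controls, all aged 17 weeks and on a C57BL/6J background per the labels. Groups were taken from the sample titles: 4 wild-type and 4 mutant muscles, and 6 wild-type and 6 mutant brains. Each of the 20 arrays carries its own mouse number in the labels, so the replicates are separate mice. Per the labels' protocols, RNA was extracted with Trizol, cleaned on RNeasy columns and turned into biotinylated cRNA with the Ambion MessageAmp kit. GenomeStudio 2011.1 is named in the submitters' processing notes.

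The deposited table of intensity values holds, for 25697 probes and each array, a signal that was neither normalized nor background-subtracted, with a detection p-value beside it in the deposited file. A further deposited table holds the authors' processed intensity values, on a linear scale. Its columns have the same probe ranks as the signals on all 20 arrays. Its lowest values, -13.3 in muscle and -14.5 in brain, show that background was subtracted. Its medians were alike within a tissue, 5.81 to 5.85 in muscle and 7.15 to 7.20 in brain, as quantile normalization within each tissue gives; no offset or log scale is involved. Those values were used only as an alternative. A platform annotation names 1 gene for 23978 probes, several for 0 and none for 1719; the last are unnamed here, not without a gene. Matching by gene identifier to the mouse RefSeq table of assembly GRCm38.p6 changed 0 symbols. That table was used for names and neighbouring genes, with no coordinates. A further gene of the title is not reported here.

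Signals were background-corrected by normexp with the negative controls inferred from the detection p-values, an offset of 16 was added, and quantile normalization and log2 followed (neqc steps of limma 3.58.1 in R 4.3.3), separately for muscle and brain. A probe was tested in a tissue when its detection p was under 0.05 on at least 4 muscle or 6 brain arrays. That left 11706 probes of 8297 named genes in muscle, 12423 probes of 8956 named genes in brain, and 10107 probes in both. Genotypes were compared within each tissue by limma (lmFit and eBayes), with Benjamini-Hochberg adjustment over the probes tested and a threshold of 0.05. The difference of the genotype effect between tissues was the interaction contrast of a limma fit to all 20 arrays. Fold changes are mutant minus wild type on the log2 scale. A gene with several probes is reported by the probe with the lowest p, and other probes of the title's genes are given apart. The offset shrinks fold changes of dim probes. Where a probe was above background on no array of a group, the fold is a lower bound: the brighter group's mean against the higher, per array, of the lowest level among detected probes and the dim probe's own level. The number of arrays limits the precision. The p-values of limma, fry and the permutation tests measure the spread between mice. Those of camera, a list test described below, set a list's genes against other genes under a preset correlation. They rest on the spread between genes and not between mice.

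Gene lists were fixed before the data were examined: 31 for muscle and 33 for brain, of which the list of the title's genes had fewer than 2 tested members and was left out of the list tests. 3 listed symbols matched no gene. Each gene was represented by its brightest tested probe. Lists were tested against all other genes by camera of limma with a preset correlation of 0.01, and beside it with a correlation estimated per list. Fry and an exact permutation test of the list's mean level per mouse were also run; both test whether the list itself shifted between genotypes, not whether it differed from other genes. The lists cover fatty acid uptake and storage, mitochondrial beta-oxidation, PPAR targets and fasting, lipogenesis, cholesterol synthesis, oxidative phosphorylation, mitophagy, autophagy and lysosome, ubiquitin and proteasome, glycolysis, the circadian clock, immediate early genes, chaperones, ER stress, antioxidant Nrf2 targets, interferon and MHC genes, RNA-binding proteins of ALS and FTD, ribosomal proteins and markers of cell types. Muscle lists also cover atrophy, denervation, fibre types, adipocytes and Schwann cells, and brain lists cover long-intron neuronal genes and markers of neurons, glia, choroid plexus and brain regions. A list of pancreatic acinar genes and a list of islet genes were added after the data were seen.

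Genes were named by a rule fixed before the data were examined: the title's genes; up to 12 raised and 12 lowered called genes by size of change; with fewer than 20 called genes, those of lowest p up to 20, said not to pass; and for each list described up to 4 members. For the interaction, up to 6 called genes per direction were named. All other called genes are also given.

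The tests were checked on simulated data with the real means and spreads and 200 changed probes. Over 11706 muscle probes, 47.0% of 1.5-fold, 82.8% of 2-fold and 100% of 4-fold changes were called. Over 12423 brain probes these shares were 53.6%, 93.8% and 100%. For the difference between tissues, over 10107 probes, they were 19.4%, 73.4% and 98.4%. Calls among unchanged probes numbered 7, 11 and 6 in these simulations. With 200 changed probes, the adjustment passes a probe at a higher unadjusted p than in the real data. The real data gave 21 called probes in muscle, 1 in brain and 5 for the difference between tissues. The simulated shares are thus likely too high for the real data. A list shifted by 0.3 in simulated brain data was the 1 list called. Noise was drawn independently for each probe, so the simulations do not show how often lists of correlated genes are called by chance. Other splits of the real arrays called a median of 4.5 lists in muscle and 2 in brain.

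Alternatives listed before the data were examined were: no background correction with a floor of 16, median scaling, normalization over all 20 arrays, the authors' values with a floor of 16, no detection filter, detection on every array, a trended robust eBayes, array weights, the replicate number as a block, leaving out each array, an adjusted p under 0.10 with a fold of at least 1.4, and 1 fit over all arrays. A slide block was planned and not run, since the slide of each array is not used here. Alternatives chosen after seeing the data were: brain without the 3 arrays that stood apart, the level of Eif2s3y or of regional marker lists as covariates, muscle without acinar probes, the exact permutation of list levels, and camera on the difference between tissues, with and without muscle wild type 2.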

Results

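Muscle and brain of 17-week-old mice carrying a human mutant TDP-43 transgene were profiled beside wild-type tissue. TDP-43, encoded by Tardbp, is an RNA-binding protein that aggregates in amyotrophic lateral sclerosis (ALS) and frontotemporal dementia (FTD). The title of the study concerns, among others, the fatty acid transporter CD36 and circulating fatty acids. There were 4 mutant and 4 wild-type muscles and 6 mutant and 6 wild-type brains. Between 11469 and 12446 of 25697 probes were above background on a muscle array and between 11736 and 12966 on a brain array. The first principal component held 40.0% of the variance in muscle and 45.4% in brain. On it, muscle wild type 2 (39.4) stood apart from the other muscle arrays, and brain wild type 2 (38.5), brain wild type 4 (41.05) and brain mutant 2 (32.7) from the other brain arrays.

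The brightest probe for mouse Tardbp was lower in mutant tissue; whether it also binds transgene RNA was not tested. This probe, ILMN_3093089, fell by 0.94 on the log2 scale in muscle (SE 0.11, limma adjusted p = 0.00533), to 52.1% of wild type, and all 4 mutants lay below all 4 wild-type mice. The exact two-sided permutation p was 0.0286, the smallest that 4 against 4 mice allow, with 0.0714 after adjustment over the 10 probe and tissue tests of the title's genes. In brain the same probe was at 67.0% of wild type, a log2 difference of -0.58 (SE 0.10). All 6 brain mutants lay below all 6 wild-type mice, with an exact permutation p of 0.00216, adjusted 0.0216, while the limma adjusted p over all brain probes was 0.145. The genotype effects on this probe differed by -0.36 between tissues (SE 0.15, limma adjusted p = 0.995).

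A Tardbp probe for another transcript, ILMN_1244811, was at 64.1% of wild type in muscle (log2 difference -0.64, SE 0.13, limma adjusted p = 0.264) and 68.3% in brain (-0.55, SE 0.15, limma adjusted p = 0.467). Its exact permutation p-values were 0.0286 in muscle, adjusted 0.0714, and 0.00866 in brain, adjusted 0.0433. ILMN_3029953, a dim Tardbp probe, differed by -0.04 in muscle and 0.12 in brain (limma adjusted p = 0.999 and 0.890), and its muscle sign turned with the authors' values to 0.11 and with array weights to 0.0068. ILMN_1228976 was above background on only 2 mutant muscles. Cd36 was above background on 0 muscle and 0 brain arrays, so this probe gives no measure of it. The limma call of Tardbp ILMN_3093089 in muscle held in 17 of 19 alternatives. It was lost with the replicate number as a block and with median scaling, where the log2 difference was -0.99 (limma adjusted p = 0.62, within a range of 2.8e-05 to 0.62). Without background correction the difference was -0.52 (limma adjusted p = 0.0257).

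**Figure D1:**
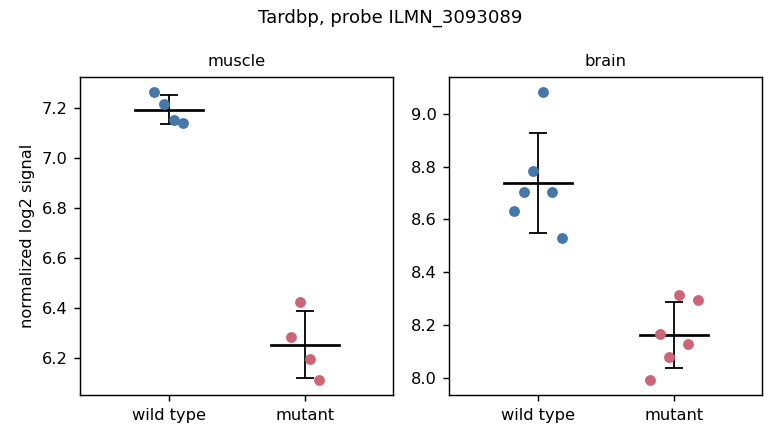
Normalized log2 signal of Tardbp probe ILMN_3093089 in each muscle (4 per genotype) and brain (6 per genotype). Points are mice, horizontal lines are means and error bars are SD. All mutants sit below all wild-type mice in both tissues.

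In muscle, 21 probes of 18 named genes passed the limma threshold, 20 lower and 1 higher in the mutant. Unadjusted p-values under 0.05 numbered 364, where 585 would be expected by chance. This number was 659 without wild type 2, the array standing apart, and 641 with array weights. It was 257 to 457 leaving out any other single array. Of the 21 probes, 17 measure digestive enzymes and other secreted proteins of the pancreatic acinar cell. Among them, Cela2a, a pancreatic elastase, fell by 2.29 (SE 0.19, limma adjusted p = 0.00174), a 4.89-fold difference. The log2 differences of other called acinar genes were -1.73 for Cela1, -1.70 for the amylase Amy2a5, -1.62 for Zg16, -1.60 for the lipase cofactor Clps, -1.60 for the trypsinogen Try10 and -1.57 for the lipase-related Pnliprp1. They were -1.56 for the ribonuclease Rnase1, -1.48 for Reg1, -1.42 and -1.39 for the carboxypeptidases Cpb1 and Cpa1, and -1.19 for Ctrl. Rnase1, Cpb1 and Cpa1 were above background on only 1 of 4 mutant muscles, Try10 on 2 and Reg1 on 3, so the level in mutants lies near background. Cela2a was called in 18 of 18 alternatives, Cela1 in 16 of 18, Cpb1 in 6 of 17 and Ctrl in 5 of 18. Try4, Sycn and Gm5409 were above background on 0 mutant muscles and were at least 2.31-fold, 1.49-fold and 1.62-fold higher in wild type. Cel (at least 1.77-fold, adjusted p = 0.0849) and Cela3b (at least 1.82-fold, adjusted p = 0.0931) were next by p and did not pass. Of 5 probes for pancreatic islet markers, 0 were detected in wild-type muscle.

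The 4 other called muscle probes were those of Rab6b, Tardbp, Rbp7 and the unnamed ILMN_1224275. Rab6b, a small GTPase of Golgi trafficking that is abundant in neurons, fell by 1.94 (SE 0.18, limma adjusted p = 0.00205). It was above background in 4 wild-type and 2 mutant muscles. Rbp7, a retinol-binding protein, rose by 1.32 (SE 0.19, limma adjusted p = 0.0205), a 2.50-fold difference and the 1 called increase. The number of called probes was 3 without background correction, 2 with median scaling, 3 with the authors' values, 8 with no detection filter and 8 with detection on every array, 13 without mutant 1 and 12 without mutant 3. The Rbp7 call was lost without wild type 1 or 4, mutant 1, 3 or 4 and without the acinar probes (adjusted p = 0.0921, 3 probes called), and it held in 9 of 19 alternatives; that of Rab6b was lost without background correction (log2 difference -0.74, adjusted p = 0.0883) and with the authors' values (-2.33, adjusted p = 0.064).

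**Figure D2:**
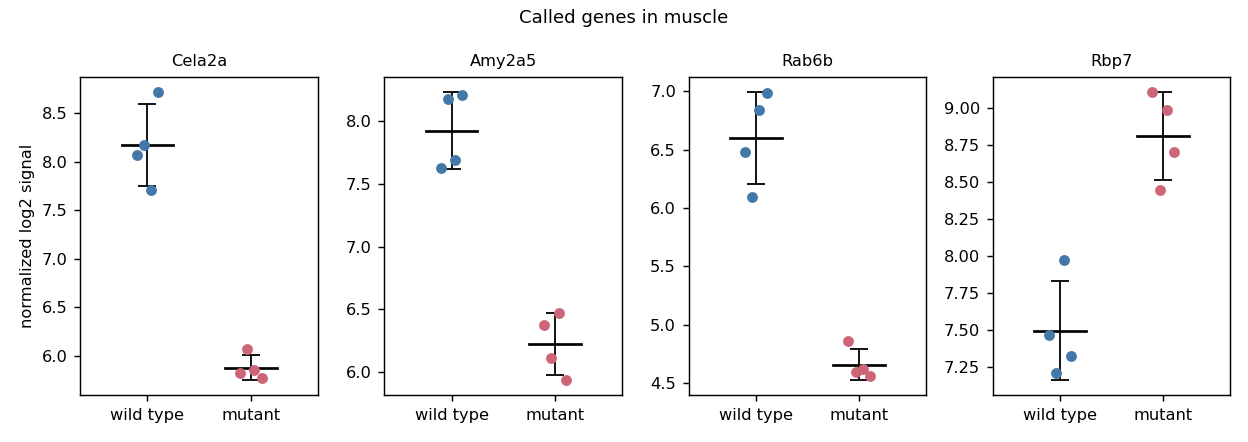
Normalized log2 signal of Cela2a, Amy2a5, Rab6b and Rbp7 in 4 wild-type and 4 mutant muscles, each panel with its own axis range. Points are mice, horizontal lines are means and error bars are SD. The genotypes do not overlap for these 4 genes, of which Rbp7 is higher in the mutant.

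Genes of the extracellular matrix and fibroblasts fell as a list in mutant muscle, with 21 of 23 measured members below wild type and a mean log2 difference of -0.33 (camera adjusted p = 1.7e-06). The adjusted p was 0.978 with an estimated correlation and 0.998 by fry, which tests the list against no change and not against other genes. Their lowest-p members were Col1a2 (-0.63), Col3a1 (-0.69), Col5a1 (-0.54) and Sparc (-0.50), collagens and a matrix protein, and 0 members passed, either over all probes or adjusted over the list alone. Macrophage markers were also lower as a list, with 16 of 18 members below wild type and a mean of -0.18 (adjusted p = 0.0199, and adjusted p = 0.978 with an estimated correlation). Their lowest-p members, none of them passing, were Tmem119 (-0.23), Mrc1 (-0.40), Cd53 (-0.24, above background on 3 wild-type and 2 mutant muscles) and Aif1 (-0.17). Leaving out single arrays, Tmem119 ranged from -0.29 to -0.15 and Aif1 from -0.25 to -0.066. Without muscle wild type 2, the array standing apart, 0 lists were called, the mean was -0.080 for the matrix list (camera adjusted p = 0.556) and 0.035 for the macrophage list, and Col3a1 was at -0.28, Col5a1 at -0.19, Sparc at -0.16, Mrc1 at -0.12 and Cd53 at -0.14. Of 16 alternatives, 12 called the matrix list and 8 the macrophage list, which was also lost without mutant 2, 3 or 4 (means of -0.28 to 0.035 leaving out single arrays).

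The other 28 muscle lists did not pass, with adjusted p-values of 0.677 or more and 0 members passing over the list alone. In lipid metabolism the mean log2 differences were 0.053 for fatty acid uptake and storage, 0.055 for beta-oxidation, 0.058 for PPAR targets and fasting, -0.078 for lipogenesis and -0.063 for cholesterol synthesis. The lipogenesis mean turned to 0.094 without muscle wild type 2. Mitochondrial and degradation lists had means of 0.036 for complex I, 0.030 for complexes II to V, 0.013 for mitophagy, 0.013 for autophagy and lysosome and 0.0086 for ubiquitin and proteasome. Muscle lists had means of -0.053 for atrophy, -0.027 for denervation, -0.014 for slow and -0.0076 for fast fibres, -0.031 for general muscle genes and -0.0025 for glycolysis. The slow-fibre mean depends on wild type 4, where the list was at 7.93 against 9.50 to 10.16 in the other wild-type muscles. Stress and regulatory lists had means of 0.035 for the clock, -0.031 for immediate early genes, -0.018 for chaperones, -0.0081 for ER stress, 0.011 for Nrf2 targets, 0.0091 for interferon and MHC genes, 0.0049 for RNA-binding proteins and 0.016 for ribosomal proteins. Cell type lists had means of 0.16 for adipocytes, -0.075 for blood, 0.00028 for endothelium and 0.10 for Schwann cells. The adipocyte mean depends on mutant 1, where the list was at 8.48 against 7.16 to 7.46 in the other mutant muscles. In 8 lists (denervation, fast fibres, clock, chaperones, Nrf2, interferon, RNA-binding and ribosomal proteins) the mean, median and test direction were not all of 1 sign.

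In brain, 1 probe passed the limma threshold: Masp2, a serine protease of the lectin complement pathway, rose by 1.18 (SE 0.12, adjusted p = 0.000932), a 2.26-fold difference. Masp2 neighbours Tardbp on chromosome 4 (assembly GRCm38.p6), and Rbp7 lies 10 protein-coding genes from it. The Y-linked Eif2s3y was detected on 6 of 12 brain arrays, 3 per genotype. Unadjusted p-values under 0.05 numbered 870, where 621 would be expected by chance. The named genes of next lowest p, which did not pass, included the autophagy enzyme Atg3 (log2 difference -0.60, adjusted p = 0.111), the myosin light chain Myl12b (-0.68, 0.111), Washc3 (-0.53, 0.145), the synaptic calsyntenin Clstn1 (-0.80, 0.239), Snu13 (-0.50), the mitochondrial pyrophosphatase Ppa2 (-0.51), Gm14325 (-0.61), the mitochondrial protease subunit Clpx (-0.56) and Art3 (-0.47, above background in 2 of 6 mutants). Padi2 (0.75, above background in 5 of 6 wild-type mice), a peptidylarginine deiminase, and the histone methyltransferase Setd1a (0.45) were higher without passing. Scg3 (-0.38), H2-T23 (-0.55, above background in 4 of 6 mutants), Slc25a16 (-0.37), Pigp (-0.41), Tmem218 (-0.41), Cd151 (-0.48) and Atp6ap2 (-0.44) completed the set. The Masp2 call was lost with regional marker levels as covariates (1.05, limma adjusted p = 0.347) and with the replicate number as a block, where 0 probes were called. The limma adjusted p of Masp2 ranged from 2.26e-05 to 0.347 over 25 alternatives, of which 23 called it. Its log2 difference ranged from 0.39 without background correction (adjusted p = 0.0133) to 1.60 with the authors' values.

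Genes of oxidative phosphorylation were lower as lists in mutant brain. For complexes II to V, 31 of 38 measured members were below wild type, with a mean log2 difference of -0.13 (camera adjusted p = 0.000107, and adjusted p = 0.0520 with an estimated correlation). The mean level of that list per mouse was 9.63 ± 0.034 (SD, n = 6) in mutants and 9.76 ± 0.063 (SD, n = 6) in wild type, with an exact permutation p of 0.00433, adjusted 0.139 over the lists. In 5 of 6 mutants it lay below all wild-type mice. Sdhb (-0.41), Cox5a (-0.26), Atp5pb (-0.31) and Sdhc (-0.31) had the lowest p. For complex I, 24 of 32 members were below wild type, with a mean of -0.092 (adjusted p = 0.0101, and adjusted p = 0.187 with an estimated correlation), among them Ndufa6 (-0.31), Ndufb5 (-0.36), Ndufs3 (-0.30) and Ndufb2 (-0.44).

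Antioxidant Nrf2 targets had 14 of 19 members below wild type and a mean of -0.10 (adjusted p = 0.0166, and adjusted p = 0.187 with an estimated correlation), with Gpx4 (-0.31), Gstm1 (-0.26), Sod2 (-0.27) and Srxn1 (-0.20) of lowest p. For mitochondrial beta-oxidation, 13 of 22 members were below wild type, with a mean of -0.098 (adjusted p = 0.0487, and adjusted p = 0.521 with an estimated correlation), among them Acot13 (-0.30), Echs1 (-0.23), Mlycd (-0.40) and Acadl (-0.34, above background in 5 of 6 mutants). Of 23 alternatives, 21 called complexes II to V, 19 complex I, 16 the Nrf2 targets and 6 beta-oxidation. Leaving out single arrays, beta-oxidation was lost without wild type 2, 3, 4 or 5 or mutant 1, 2, 3 or 5 and Nrf2 targets without wild type 3 or mutant 6, with means of -0.12 to -0.077 for both lists. In these 4 lists 0 members passed over all probes or adjusted over the list alone. Levels of regional marker lists also differed between mice: the cerebellum list was at 6.22 in brain wild type 6 against 7.43 to 7.88 in the other brains, and the hypothalamus and pituitary list ranged from 6.00 in brain wild type 1 to 8.14 in brain mutant 1. With the regional levels as covariates, complex I (mean -0.065, adjusted p = 0.182) no longer passed and complexes II to V (-0.095, adjusted p = 0.0182) did.

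**Figure D3:**
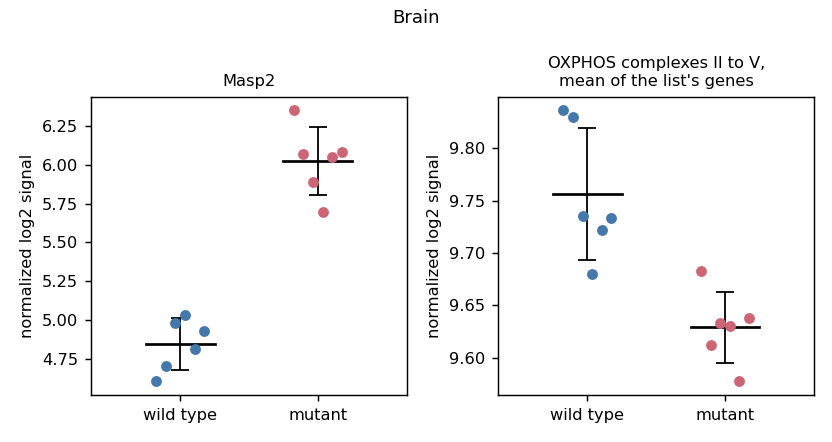
Normalized log2 signal of Masp2 and mean log2 signal of the 38 genes of oxidative phosphorylation complexes II to V in 6 wild-type and 6 mutant brains, each panel with its own axis range. Points are mice, horizontal lines are means and error bars are SD. Masp2 does not overlap between genotypes, and in 5 of 6 mutants the list mean is below all wild-type mice.

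The other 28 brain lists did not pass camera, with adjusted p-values of 0.322 or more. Single members passed when adjusted over the list alone, though not over all probes: the malic enzyme Me1 (-0.48) in lipogenesis, the coactivator Ppargc1b (0.74) among PPAR targets, the neurofilament gene Nefm (-0.59) among neuronal and RNA-binding-protein lists, and the chaperone Hspa4l, above background in 0 mutants and at least 1.14-fold higher in wild type. Means were 0.00065 for fatty acid uptake, 0.060 for PPAR targets, -0.062 for lipogenesis, -0.048 for cholesterol synthesis, -0.038 for mitophagy, -0.076 for autophagy and lysosome, -0.045 for ubiquitin and proteasome and 0.0065 for glycolysis. By fry, which tests for a shift from no change and not against other genes, autophagy and lysosome (adjusted p = 0.0251), ubiquitin and proteasome (0.0227) and complexes II to V (0.0152) passed. Further means were -0.073 for the clock, -0.00028 for immediate early genes, 0.016 for chaperones, 0.045 for ER stress, -0.030 for interferon and MHC genes, -0.022 for RNA-binding proteins, 0.027 for long-intron neuronal genes and -0.043 for ribosomal proteins. Cell type means were 0.057 for neurons, 0.027 for astrocytes, -0.0090 for oligodendrocytes, 0.031 for microglia, -0.013 for endothelium, 0.040 for blood, -0.0094 for fibroblasts, 0.014 for choroid plexus and 0.039 for monoamine and cholinergic neurons. Regional means were 0.40 for hypothalamus and pituitary, -0.024 for striatum and 0.19 for cerebellum. The cerebellum mean depends on wild type 6, where the list was at 6.22 against 7.43 to 7.88 in the other brains. In 11 lists (fatty acid uptake, clock, immediate early, chaperones, fibroblasts, endothelium, neurons, oligodendrocytes, choroid plexus, striatum, monoamine) the mean, median and test direction were not all of 1 sign.

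The genotype effect differed between muscle and brain for 5 of 10107 probes by the limma interaction test, with 437 unadjusted p-values under 0.05 where 505 would be expected by chance. Rab6b (muscle -1.94, brain -0.10, difference -1.84, adjusted p = 4.4e-05), Cela1 (difference -1.67, adjusted p = 0.000638), Ctrl (-1.26, 0.00674) and the chymotrypsinogen Ctrb1 (-0.87, 0.0321, above background on 1 of 4 mutant muscles) had the more negative effect in muscle. Myl12b had the more positive one, 0.43 in muscle and -0.68 in brain (difference 1.11, adjusted p = 0.0321). Of these, Rab6b was called in 27 of 28 alternatives, Cela1 in 28 of 29, Ctrl in 26 of 29, Myl12b in 10 of 29 and Ctrb1 in 8 of 28 (-0.24 without background correction, adjusted p up to 0.978). The count was 1 without background correction and 1 with median scaling. No probe was called in both tissues by limma, and across genes, which are not independent replicates, the fold changes correlated with r = 0.054 and rho = 0.033.

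For the lists fixed for both tissues, the effects on complexes II to V differed by 0.16 (camera adjusted p = 0.000718, and adjusted p = 0.0719 with an estimated correlation), on complex I by 0.13 (0.0145, and adjusted p = 0.372 with an estimated correlation) and on beta-oxidation by 0.17 (0.0126, and adjusted p = 0.447 with an estimated correlation), muscle minus brain. Fibroblast genes differed by -0.33 (adjusted p = 0.000195, and adjusted p = 0.447 with an estimated correlation) and macrophage markers by -0.20 (adjusted p = 0.0363, and adjusted p = 0.730 with an estimated correlation). Nrf2 targets did not pass (0.14, adjusted p = 0.0736). Without muscle wild type 2 the difference was -0.058 for fibroblast genes (adjusted p = 0.639) and 0.033 for macrophage markers (adjusted p = 0.917), neither passing, while Nrf2 targets passed (0.18, adjusted p = 0.0295, and adjusted p = 0.139 with an estimated correlation). These list tests were chosen after the data were seen.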

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

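The tests of the acinar transcripts for pancreatic RNA and for background correction were chosen after the result was seen; the test on single arrays and the counts over other splits were set before. Of 164 groups of values screened for a sample far from the others, 9 stood out, where chance flags about 8.2.

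Acinar transcripts were higher in all 4 wild-type muscles: the mean log2 level of the tested acinar probes was 5.85, 6.14, 5.74 and 6.44 in wild type 1 to 4 and 4.79, 4.81, 4.78 and 4.77 in mutants 1 to 4, and of 23 tested acinar probes 22 were lower in the mutant, while Cuzd1 was not (0.21), and 0 of 5 islet probes were detected in wild-type muscle. A single array does not account for it, since at least 9 of the 17 called probes stayed called whichever array was left out. Background correction or normalization is not the whole cause. In the deposited signals, before either step, the 23 probes had a median log2 difference of -0.49, and the 6 uncalled ones had -0.25. The mean log2 signal of the 23 was 6.97 to 7.77 in wild type and 6.74 to 6.82 in mutants. As low a median was found in 0% of 1000 random lists of like signal (lowest -0.10). That share is partly built in, since the acinar list was drawn up after the data were seen. Also, all 23 probes were detected on all 4 wild-type muscles but only 8 on all 4 mutants. Wild type alone was thus enough to carry all 23 past the detection filter, and the mutants alone only 8. Sizes and calls varied with correction and normalization. The median of -1.39 became -0.45 without correction, which leaves the background in the signal, -1.40 with median scaling and -1.45 with the authors' values. In that order 2, 1 and 2 acinar probes were called, and Cela1 went from -1.73 (SE 0.16) to -0.65 (SE 0.08), -1.74 (SE 0.25) and -2.15 (SE 0.17). Pancreatic RNA or tissue in the wild-type samples is a candidate explanation that was not decided here. Over the 4 wild-type arrays the mean correlation between 21 acinar genes was 0.725, above 100% of 1000 random lists of like signal (their median was -0.013). The random lists held unrelated genes, and acinar genes expressed together in muscle could correlate as well. The correlation therefore does not tell pancreatic RNA from a genotype effect on acinar genes expressed in muscle, which stays open and untested. Cela1 and Ctrl were also detected on all 12 brain arrays.

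Other splits of the same arrays bear on whether chance alone gives such counts. In muscle, 1 of 35 splits, the real one, gave 21 or more probes, and the highest other split gave 2. Chance alone is thus unlikely to give the muscle count, though 1 of 35 is the smallest share possible here. For the difference between tissues, 1 of 100 drawn splits, the real one, gave 5 probes. The highest other gave 4, a margin too small to exclude chance, and 3 of the 5 probes are acinar. The real count itself was 1 without background correction and 1 with median scaling. In brain, 5 of 100 drawn splits gave 1 or more probes, the highest other 2, so chance cannot be excluded for the brain count. For gene lists, 30 of 35 muscle splits gave 2 or more lists (highest other 13), and 37 of 100 brain splits gave 4 or more (highest other 9). Chance cannot be excluded for either, and why so many splits call lists was not tested.

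Among samples far from their group, muscle wild type 2 had the highest Col5a1 (9.68 against 8.25 to 8.33), Sparc (11.48 against 9.98 to 10.20) and mean level of the matrix and fibroblast list (8.90 against 7.87 to 7.93). Pnliprp1 was at 7.24 in muscle wild type 4 against 6.19 to 6.33 in the others, and Cela1 at 5.02 in muscle mutant 3 against 4.63 to 4.65. In brain, Mlycd was at 7.39 in wild type 1 against 6.52 to 6.76, Ndufb5 at 6.22 in mutant 5 against 6.66 to 6.88, and in mutant 2 Gstm1 was at 9.21 against 8.64 to 8.83 and Me1 at 6.43 against 5.79 to 5.99. Effects that differed between tissues, muscle minus brain by the limma interaction, were those of Rab6b (-1.84), Cela1 (-1.67), Ctrl (-1.26), Ctrb1 (-0.87) and Myl12b (1.11).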

How the results depend on the processing

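Apart from the Tardbp probes, 1721 values of single genes and lists were taken under alternatives. Of these, 1519 kept their direction and side of the threshold, 192 fell below it, 9 rose above it and 1, the macrophage list, reversed. Many of the 1721 belong to genes that did not pass in the main analysis and so could not fall below the threshold. The 1519 therefore do not measure how often a call held. The alternatives of brain region, Y-linked level, arrays apart, acinar probes and permutation were chosen after seeing the data. For the dim probes of Cela1 and Rab6b, near background, fold changes depended on the background correction (-0.65 and -0.74 without it). The cause was not tested for the following changes except where fewer arrays or probes were used. Called probes in muscle numbered 21, and 3 without background correction, 2 with median scaling, 3 with the authors' values, 8 with no filter, 8 with detection on every array, 12 with the replicate block, 3 without acinar probes, and 12 to 23 leaving out single arrays (13 without mutant 1, 12 without mutant 3). In brain they numbered 1, and 2 without background correction, 2 with the authors' values, 2 with detection on every array, 2 with trend and robust, 5 with array weights, 0 with the replicate block (1201 at an unadjusted p under 0.05 by limma), 2 in the fit to all 20 arrays, 2 without the 3 arrays apart, 0 with regional levels as covariates (343 at an unadjusted p under 0.05), 2 at an adjusted p under 0.10 with a 1.4-fold change, and 1 to 2 leaving out single arrays (2 without wild type 3). For the difference between tissues they numbered 5, and 1 without background correction, 1 with median scaling, 25 with no filter (more probes tested), 3 with detection on every array, 2 with the replicate block and 3 to 6 leaving out single arrays, where 12 of the 20 arrays gave 3. With median scaling the median of all probes was -0.20 in brain and 0.19 in the difference between tissues, against 0.0026 and 0.011. Lists called in muscle numbered 2, and 0 with an estimated correlation, 0 by fry, 0 by permutation, 1 with the mean of all probes, and 0 to 4 leaving out single arrays (0 without wild type 2, 4 without wild type 4, 1 without mutant 2, 3 or 4); the macrophage list ranged from -0.28 to 0.035. Lists called in brain numbered 4, and 0 with an estimated correlation, 0 by permutation, 8 with median scaling, 2 with the mean of all probes, and 2 to 5 leaving out single arrays (2 without wild type 3). Tardbp ILMN_3093089 in muscle missed the threshold with median scaling (-0.99, adjusted p = 0.62) and the replicate block (-0.94, adjusted p = 0.0560), and in brain passed it in the fit to all 20 arrays (-0.58, adjusted p = 0.0229, within a range of 0.0229 to 1.00 over alternatives). ILMN_3029953 in muscle turned sign in 4 alternatives, with the authors' values (0.11) and array weights (0.0068) and without mutant 2 or 4, and ranged from -0.17 to 0.017 leaving out single arrays. Same-numbered samples are different mice, so the numbers do not pair samples of 1 mouse. Their correlations were 0.014, -0.23, 0.10 and -0.25 in muscle and 0.22, 0.62, 0.29, -0.070, 0.24 and -0.0035 in brain. Whether samples of the same number shared a batch was not tested, and the brain values leave it open. The slide block was not run.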

Other observations

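The tests here of the neighbourhood of Tardbp for chance placement and of Eif2s3y were chosen after the values were seen; the test of different DNA was set before its result.

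Masp2 and Rbp7, called in brain and in muscle, lie near Tardbp on chromosome 4 in assembly GRCm38.p6: Masp2 is the next protein-coding gene and Rbp7 is 10 protein-coding genes away. In the 10 tested genes on each side of Tardbp, 8 of 20 had an unadjusted p under 0.05 in either tissue (Agtrap, Mad2l2, Fbxo44, Exosc10, Masp2, Pex14, Cort and Rbp7), against a median of 2 elsewhere. As many were found in 0.0635% of 9444 other windows, and as many as the 6 left without Masp2 and Rbp7 in 1.59%, which argues against chance placement. DNA around Tardbp that differs between the genotypes may be a source, as a hypothesis; the fold changes of muscle and brain over the 16 genes tested in both correlated with r = 0.215, at percentile 72.2 of other windows, which leaves it open. A local effect of an altered Tardbp locus, or a probe that binds a variant, was not tested.

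Eif2s3y, a Y-linked gene, was near background on 6 of 12 brain arrays, 3 wild-type and 3 mutant (signals 99.2 to 109), and at 151 to 327 on the other 6; all 8 muscle arrays had 247 to 759. The series text states male mice. As to weak hybridisation, 5 of the 6 arrays detected more probes than the lowest of the others, a low bar set by a single array. The 6 arrays detected 11736 to 12648 probes against 11933 to 12966 on the others. The ranges overlap, and somewhat weaker hybridisation is not excluded. Female mice among the brain samples is a candidate explanation: on both Xist probes each of these 6 arrays exceeded all brain arrays with Eif2s3y in signal over the array median, with 0 exceptions (6.17 to 23.3 against -8.58 to 3.50 on ILMN_3123341). Kdm5d was detected on 5 of the arrays with Eif2s3y and 0 of those without, but Uty, also Y-linked, on 6 and 5 (signals 111 to 140 and 103 to 117). Both probes are dim and decide little. On muscle wild type 3, which had Eif2s3y, neither was detected, and on muscle mutant 3, which also had it, Uty was not. The sex of these mice stays open. With Eif2s3y as a covariate 1 probe was called in brain.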
